A study of Mus musculus with 4 samples.

How the data were processed

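The data were 4 single-cell RNA libraries of live CD41-positive cells of wild-type C57/BL6 mice, 1 each from adult bone marrow, adult lung (both week 10), fetal liver and fetal lung (both embryonic day 13). Per the labels, the top 1 percent of CD41-APC events were sorted and captured with droplet 3' v3 chemistry. The authors deposited a matrix of UMI counts per gene and barcode for each library. Per the submitters' processing notes, those counts were made with Cell Ranger 3 on genome build GRCm38, and Seurat is also listed. Only the counts were used here. The matrices held whole counts for 31053 genes in 2980, 2093, 2664 and 1879 barcodes (adult bone marrow, adult lung, fetal liver, fetal lung), with 42791745, 25273288, 58894318 and 43529632 UMIs. Symbols that occurred more than once were told apart by an added number, and 30934 gene IDs were found in the reference annotation, which gave the positions.

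Barcodes with fewer than 500 genes, or with more than 15% of UMIs from mt- genes, were left out: 409, 146, 579 and 146 barcodes, of which 384, 90, 537 and 105 had high mt- shares. Doublets were scored with Scrublet within each library. The cells with the highest scores, 0.8% per 1000 barcodes, were left out (61, 33, 44 and 26 cells), and doublets of like cells, or of cells joined before capture, would not be found this way. The 8172 kept cells of all libraries were clustered together with scanpy 1.11.5 (anndata 0.12.19, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen without the 352 genes of the fixed lists. 30 principal components, 15 nearest neighbours and the Leiden method (leidenalg 0.10.2, igraph 0.11.9, resolution 1) gave 43 clusters. No integration across libraries was made, because library and tissue are the same factor here, so a cluster held mostly by 1 library may reflect that library.

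Clusters were named from 19 marker classes: the class with most markers among the cluster's 10 most raised genes (seen in 25% of its cells or more), then by number of raised markers (2-fold or more, in 10% of cells or more, at least 3 markers). Of the 43 clusters, 8 were named megakaryocyte-like and 0 were left unnamed. Names carry the ending -like because they rest on RNA only. A choice was made after the first names were seen: the reference for a raised gene was switched from all other cells to the median of the other clusters, because the first reference left fetal liver cluster 0 unnamed and called bone marrow clusters 10 and 17 progenitor-like. Cluster 28 had few genes per cell and kept its name because its top genes were mostly megakaryocyte markers. Comparisons, marker classes, gene lists, the rule for named genes and the filters were fixed before the data were examined.

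UMIs of the megakaryocyte-like cells were summed per library and scaled to CPM by the sum over all genes. Ratios are log2((CPM+5)/(CPM+5)), so the pseudocount is 5 CPM. There are 4 comparisons: adult lung over adult bone marrow, fetal lung over fetal liver, adult lung over fetal lung, and adult bone marrow over fetal liver. With 1 library per group no test was possible and none was made, and cells were not treated as replicates. CPM have exact Poisson intervals, shares of cells have Clopper-Pearson intervals, and list medians have intervals from 1000 Poisson draws, all at 95% and all for counting error only.

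The 19 fixed lists were MHC class II presentation, MHC class I presentation, co-stimulation and leukocyte receptors, innate sensors, cytokines and chemokines, interferon response, immediate-early and heat shock genes, S phase, G2/M phase, fetal programme and imprinted growth genes, megakaryocyte transcription factors, platelet granules and secretion, cytoskeleton and proplatelet, platelet signalling, growth factors and matrix, oxidative phosphorylation, glycolysis, secretory pathway and unfolded protein response, and sex-linked genes. A member counts as measured with 10 or more UMIs over both libraries. Each median was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins, and this percentile describes the 4 libraries only. Members are called higher or lower at a 2-fold difference. Where a member had 0 UMIs on 1 side, the list median is also given with that member set to 3 UMIs, the floor. That member's ratio was then taken without the pseudocount, which the other members kept. A median at the floor can therefore lie further from 0 than the first median, and part of its shift comes from the dropped pseudocount. A fold against 0 is given as a lower bound against this floor, set over the summed cells of the library. List members Ifi30, Clec7a, Vps16b and Ahsp were not found in the files under these symbols.

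The marker classes were treated as lists in the same way, and those with results beside the comparisons are named there. Megakaryocyte markers also named the clusters that were compared, so their medians are not independent of that choice of cells. In adult lung over adult bone marrow, stem or progenitor markers had a median of -1.27 (2.00 with members at the floor), endothelial 0.41 (1.97), erythroid 0.56 (3.93), dendritic -1.52 (2.14), basophil or mast -0.36 (5.60), granulocyte-monocyte progenitor -0.66 (4.45), lung epithelial -0.27 (6.09) and hepatocyte markers -0.16 (4.35). Where the sign turned in this way, no direction could be read. The values in brackets are medians at the floor here as well, given where they differ. In fetal lung over fetal liver, dendritic markers had 0.34, stem or progenitor 0.09, basophil or mast 0.22, neutrophil -0.16 (0.26), granulocyte-monocyte progenitor -0.47 (-0.49), endothelial 0.15, lung epithelial 0.02 and hepatocyte markers -0.30 (0.06). In adult lung over fetal lung, stem or progenitor markers had 0.60 (1.00), endothelial -0.36 (0.51), dendritic -0.80 (3.39), basophil or mast -1.94 (2.23) and mesenchymal markers -1.62 (2.70), of which all 8 were at 0 in adult lung. In adult bone marrow over fetal liver, macrophage markers had 0.14, monocyte -0.19, granulocyte-monocyte progenitor 0.21, basophil or mast -0.19, dendritic -0.10, mesenchymal -0.27 (-1.85), T -0.12 (-0.45), NK 0.05, lung epithelial 0.17, hepatocyte -0.26 (-0.79) and neural markers -0.04. Mesothelial and eosinophil markers had too few measured members in every comparison.

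Named genes followed a fixed rule: among genes with 20 CPM or more in a library and 30 UMIs or more over both, the 10 highest and 10 lowest ratios, without mt-, ribosomal protein, predicted and sex-linked genes, and up to 4 members of each list by size of ratio. Itga2b, Pf4, Ppbp, Gp9 and Vwf were always given. Some genes that these rules chose are not reported here. Genes followed in single cells (Cd74, Igkc, Cd79a, C1qa, H2-K1, H2-DMa) were chosen after their values were seen. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs and without thinning.

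The steps were tested on simulated data. For adult lung over adult bone marrow, 64.5%, 85.1% and 93.5% of genes given a true 2-fold, 4-fold and 8-fold difference were found (0.75 or more on the log2 scale in the right direction), and 24.9% of genes with no difference were 2-fold or more apart. For adult lung over fetal lung the shares were 62.0%, 92% and 98.1%, with 24.0% of genes with no difference apart. For fetal lung over fetal liver they were 83.3%, 100% and 100%, and for adult bone marrow over fetal liver 92.6%, 100% and 100%, with 0% of the genes with no difference apart in both. The libraries of each comparison were drawn from their pooled profile with counting error only. RNA held unevenly by a few cells and differences between libraries were not simulated, so these shares do not cover them. Cluster naming gave the simulated class in 98.3% of 2843 cells drawn from the 43 clusters and in 86.3% of 1200 cells of 8 classes, where none of the dendritic cells was named so. The simulated class was the name that the same rule had given the source cells. These shares therefore show how far the names repeat, and not that they are right. Adult lung megakaryocyte-like cells (4 in cluster 9 and 5 in cluster 28) were too few to be drawn.

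Alternatives from that same plan were a loose and a strict cell filter, doublets kept, Leiden resolutions 0.5 and 2, lists left in the clustering genes, cells taken by 6 or more megakaryocyte markers, totals without mt-, ribosomal and haemoglobin genes, median of ratios scaling, the mean of each cell's CPM, thinning, pseudocounts of 1 and 20 CPM, members with 50 or more UMIs and the part of the megakaryocyte-like cells with the higher marker share. Added after seeing the data were cluster 9 alone, leaving out adult lung cells with 5 or more UMIs of B or plasma, macrophage and dendritic markers, leaving out bone marrow cells with 5 or more Igkc, Ighm and Jchain UMIs, members above the floor, fetal lung macrophage-like cells without cluster 15, bone marrow megakaryocyte-like cells without cluster 40, and clusters named by fold over all other cells. Per-cell values of the 9 adult lung cells, and list sums in them with and without the cells with leukocyte marker UMIs, were also choices made after seeing the data. Figures were drawn with matplotlib 3.10.9.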

Results

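CD41-sorted cells of wild-type C57/BL6 mice were profiled by droplet 3' RNA sequencing in 4 libraries: bone marrow and lung of adults at week 10, and liver and lung of embryos at day 13. Each tissue and age had 1 library, so there were no replicates, no test was possible, and every interval below is a 95% interval for counting error only. The libraries held 2510 (adult bone marrow), 1914 (adult lung), 2041 (fetal liver) and 1707 (fetal lung) cells after filtering. Median depth was 10984, 10736, 24044 and 18484 UMIs per cell in that order, with 2524, 3095, 4740 and 4253 genes detected per cell.

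Itga2b RNA, which encodes CD41, the protein that the sort gate read (ENSMUSG00000034664, chromosome 11, 102453297 to 102470122 on the minus strand), was present in all 4 libraries. It was not seen in every sorted cell, so the RNA did not simply follow the gate. It stood at 418 CPM (412 to 424) in adult bone marrow, 48.5 (45.8 to 51.4) in adult lung, 695 (688 to 702) in fetal liver and 473 (466 to 479) in fetal lung. With every cell thinned to 2000 UMIs, Itga2b was seen in 18.3%, 4.58%, 56.6% and 32.5% of cells, and without thinning in 24.4%, 10.3%, 85.3% and 52.7%. Thinning left out 179, 80, 32 and 83 cells. In cell types that should lack Itga2b, the thinned share was 0.923% in bone marrow neutrophil-like cells (median 4497 UMIs), 0.855% in adult lung endothelial-like cells (16786), 16.9% in fetal liver endothelial-like cells (12298) and 2.70% in fetal lung endothelial-like cells (34134). In the cells named megakaryocyte-like, Itga2b reached 887 CPM (874 to 901) in adult bone marrow, 3826 (3277 to 4440) in adult lung, 813 (804 to 821) in fetal liver and 2761 (2698 to 2824) in fetal lung. The thinned share of those cells was 76.6%, 100%, 73.2% and 97.7%. Pf4, a platelet chemokine gene on chromosome 5 (90772435 to 90773383), stood at 15053, 17359, 20396 and 31143 CPM in the same cells. Ppbp stood at 309, 6103, 1152 and 3807 CPM, Gp9 at 207, 2366, 559 and 2538, and Vwf at 310, 907, 250 and 461.

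The sort gate gave very different cell mixtures in the 4 tissues. Megakaryocyte-like cells made up 70.7% of kept fetal liver cells (68.7 to 72.7; 1444 cells) and 19.8% of adult bone marrow cells (18.3 to 21.4; 497 cells). In the lungs they were fewer: 13.8% in the fetus (12.2 to 15.6; 236 cells) and 0.470% in the adult (0.215 to 0.891; 9 cells). Macrophage-like cells were the most numerous class of both lung libraries, and neutrophil-like cells of the bone marrow library.

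Adult lung cells were 50.3% macrophage-like (48.0 to 52.6), 19.96% endothelial-like (18.2 to 21.8), 11.6% dendritic-like (10.2 to 13.1), 6.74% B or plasma-like and 5.80% mesenchymal-like. Fetal lung cells were 42.5% macrophage-like (40.1 to 44.9), 22.3% mesenchymal-like (20.4 to 24.4) and 17.3% endothelial-like (15.6 to 19.2). Adult bone marrow held 44.2% neutrophil-like (42.2 to 46.2), 10.9% monocyte-like, 8.45% granulocyte-monocyte progenitor-like, 7.93% B or plasma-like and 2.79% basophil or mast-like cells. Fetal liver held 12.7% endothelial-like, 4.21% macrophage-like and 3.72% erythroid-like cells. No cell of 2041 was named neutrophil-like in fetal liver, where 3 cells would have been 0.147%. Smaller classes were lung epithelial-like cells (2.77% of adult and 2.40% of fetal lung), hepatocyte-like cells (0.735% of fetal liver) and T-like cells (20 in adult lung and 17 in bone marrow). Itga2b was found beyond megakaryocyte-like cells, at 279 CPM in bone marrow basophil or mast-like cells, 591 CPM in fetal lung macrophage-like cells and 587 CPM in fetal liver macrophage-like cells. Adult lung macrophage-like cells held 64.2 CPM of Itga2b and 2750 CPM of Pf4. The megakaryocyte-like share depended on the definition. With cells taken by 6 or more detected megakaryocyte markers it was 6.84% in adult lung, where 60.3% of those cells lay in macrophage-like clusters, and 43.8% in fetal lung, where 50.4% did. With clusters named by fold over all other cells it was 1.71% in adult bone marrow and 38.5% in fetal liver, and the adult lung share was 1.12% under a loose and 0.166% under a strict cell filter.

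**Figure D1:**
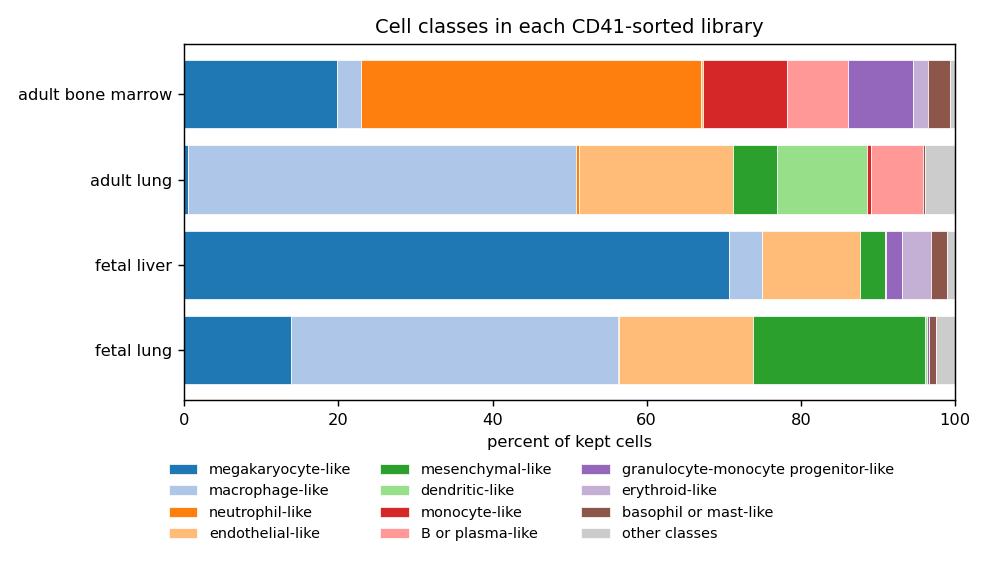
Share of kept cells per named class in each library. Megakaryocyte-like cells made up 19.8% in adult bone marrow, 0.470% in adult lung, 70.7% in fetal liver and 13.8% in fetal lung.

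Megakaryocyte-like cells lay in different clusters in the 4 libraries. In adult bone marrow, clusters 10 and 17 held 240 and 208 of the 497 cells, and in fetal liver, clusters 0, 2, 19 and 9 held 658, 495, 160 and 120 of the 1444. Cells of both lungs shared clusters 9 and 28, with 4 and 5 cells in the adult and 128 and 82 in the fetus. Cluster 28 in fetal lung had a median of 950 genes per cell, against 5374 over all bone marrow megakaryocyte-like cells. It held 1.69 Gata1 UMIs per 100 Itga2b UMIs, against 11.1 in cluster 9. Whether its barcodes were nucleated cells was not tested, and the shares and sums of both lungs include them. Summed over cells, the class held 18453133 UMIs in bone marrow, 45222 in adult lung, 44506348 in fetal liver and 2691640 in fetal lung. The floor used for genes at 0, 3 UMIs, therefore corresponded to 66.3 CPM in adult lung and to 0.163, 0.0674 and 1.11 CPM in the others. UMIs of Xist and of the Y-linked genes Ddx3y and Eif2s3y occurred together in the megakaryocyte-like cells of all 4 libraries, and the sex-linked list had medians between -0.81 and 0.04 on the log2 scale. In the 2 comparisons of adult lung it had 1.51 and 0.88 with members at the floor.

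Adult lung against adult bone marrow was the first comparison of megakaryocyte-like cells. Genes of MHC class II antigen presentation were higher by size in the adult lung cells, and so were platelet cytoskeleton genes. Cell cycle, secretory pathway and respiratory chain genes were lower by size. The MHC class II RNA was uneven: 2 of the 9 adult lung cells held 89.8% (85.0 to 93.5) of the 216 UMIs of H2-Aa, H2-Ab1, H2-Eb1 and Cd74, and those 2 cells also held B cell transcripts.

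Cd74, which encodes the invariant chain (chromosome 18, 60803848 to 60812652), stood at 2278 CPM (1859 to 2762) in adult lung against 49.2 (46.0 to 52.5) in bone marrow. H2-Aa (chromosome 17, 34282744 to 34287823) stood at 951 against 17.8 CPM, H2-Ab1 (34257689 to 34269419) at 885 against 29.8 and H2-Eb1 (34305867 to 34316674) at 663 against 17.1. Over the 12 measured members of the list, the median log2 ratio was 4.33 (3.60 to 4.76), above every one of 10000 matched random lists. By size, 11 members were at least 2-fold higher and 0 lower, among them the protease gene Ctss at 6.10, with 28 of its 30 UMIs in 1 cell. Cd74 UMIs were present in 62.5% of 8 thinned megakaryocyte-like cells and in 60% of 5 thinned adult lung neutrophil-like cells, a type that should hold little. Unthinned, the shares were 66.7% of 9 and 62.5% of 8, with median depths of 4782 and 2074.5 UMIs, and thinning left out 1 and 3 cells. Cells 1 and 2 by MHC class II UMIs held 39 and 33 UMIs of Igkc, an immunoglobulin gene, and 7 and 11 of Cd79a, and cell 3 held 54 UMIs of the complement gene C1qa. Without the 5 cells that carried 5 or more UMIs of B or plasma, macrophage and dendritic markers, the list summed to 675 CPM (292 to 1331) from 8 UMIs in 4 cells, and its median was -0.65. Only 11847 of the 45222 UMIs were then left, so most members were at 0 by depth and the median had to fall, while a sum in CPM does not fall with depth. The 5 cells summed to 8030 CPM (7097 to 9051), 11.9 times (5.95 to 27.8) the level of the 4 others. The sum was 596 CPM (286 to 1097) in adult lung neutrophil-like cells and 218 CPM (212 to 225) in bone marrow megakaryocyte-like cells.

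**Figure D2:**
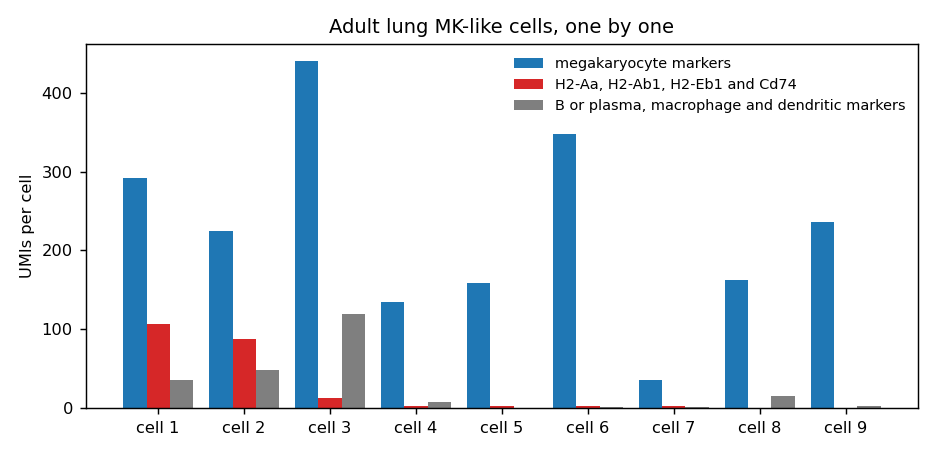
UMIs of megakaryocyte markers, of 4 MHC class II genes and of B cell, macrophage and dendritic markers in each of the 9 adult lung megakaryocyte-like cells. Cells 1 and 2 held 107 and 87 of the 216 MHC class II UMIs, beside 292 and 225 megakaryocyte marker UMIs.

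The co-stimulation and leukocyte receptor list had a median of 3.58 (12 measured, 10 higher and 0 lower, with Cd86 4.51, Cd52 4.23, Fcgr1 4.12). It summed to 3056 CPM (2492 to 3710) in those 5 cells, 1266 (709 to 2088) in the 4 others and 301 in bone marrow. Cytokines and chemokines had 1.496 (-0.25 to 2.12; 8 of 14 higher, 1 lower, with Cxcl2 5.81, Tnf 4.01, Ccl9 3.64), 3.38 with 4 members at 0 set to the floor, and -0.41 under the strict cell filter, which left 3 cells. They summed to 2577 CPM in the 5 cells, 929 (464 to 1661) in the 4 others and 549 in bone marrow. MHC class I presentation had -1.24 (-2.23 to -0.65; 2 of 15 higher, 8 lower, -0.37 with 4 members at the floor, and 0.09 in cells with 6 or more markers), with H2-Q7 at -3.83, H2-T23 at 1.46 and B2m at 1.19. Its sums, 4312 CPM (3728 to 4962) in adult lung and 3915 (3886 to 3943) in bone marrow, did not differ beyond counting error. Immediate-early genes had 0.92 (11 of 22 higher, 7 lower, and 1.21 with 2 at the floor), with Nr4a1 at 3.05, Junb at 2.67 and Hsp90aa1 at -2.78, but -0.57 under median of ratios scaling. They summed to 9978 CPM (8935 to 11109) in the 5 cells, 1097 (584 to 1876) in the 4 others and 8199 in bone marrow. Over all 9 cells the sum was 7651 (6866 to 8501). For the innate sensor (-0.24), interferon response (-1.24), fetal programme (-0.50) and growth factor (-0.31) lists, most members were at 0 UMIs in adult lung. Setting them to the floor gave 3.49, 2.79, 2.54 and 4.82, so no direction could be read from these medians. Growth factors summed to 1459 CPM (1129 to 1857) in adult lung, with 1351 (772 to 2193) in the 4 other cells, against 316 (308 to 324) in bone marrow. Interferon response genes summed to 597 (393 to 869) against 1221 (1205 to 1237). The sums of the innate sensor and fetal programme lists did not differ beyond counting error. Cd14 at 4.13, Ifi27l2a at 3.66 and Fn1 at 6.47 were the largest ratios in those lists, and all 24 Fn1 UMIs lay in cell 3.

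Platelet cytoskeleton and proplatelet genes had a median of 1.68 (1.31 to 1.86; percentile 98.2), with 12 of 19 members higher and 2 lower, and 0.12 under median of ratios scaling. Tpm4 stood at 3.84, Pdlim1 at 3.38, Flna, the filamin gene, at 3.14 and Mylk at 2.95. Megakaryocyte markers themselves had 2.05 (13 of 18 higher, 1 lower; Tubb1, the platelet tubulin gene, 5.24, Alox12 4.89, Ppbp 4.28). Granule genes had 0.72 (-0.06 to 1.17; 9 of 18 higher, 5 lower, and 1.09 with 3 at the floor, with Thbs1 5.05, Clu 3.55, Timp3 -3.48). Platelet signalling genes had 0.80 (9 of 21 higher, 5 lower, and 0.88 with 4 at the floor, with P2ry12 4.26). Under median of ratios scaling both medians were negative, at -0.74 and -0.77. Among megakaryocyte transcription factors the median was -0.30 (3 of 17 higher, 5 lower, and -0.05 with 4 at the floor), with Nfe2 at 1.86 and Meis1 at 0 UMIs in adult lung. S phase genes had -3.76 (0 of 23 higher, 23 lower, and -0.64 with 19 at the floor) and G2/M genes -4.41 (0 of 24 higher, 24 lower, and -0.84 with 22 at the floor). Secretory pathway genes had -2.97 (-3.77 to -2.72; 0 of 18 higher, 17 lower, and -1.62 with 6 at the floor), but -0.61 in cells with 6 or more markers. Pdia3 stood at -4.03, and Pdia6, Sdf2l1 and Atf4 were at 0 UMIs in adult lung. Respiratory chain genes had -1.59 (0 of 20 higher, 12 lower, with Atp5g1 -3.43, Uqcrc1 -3.07) and glycolysis genes -1.15 (4 of 16 higher, 8 lower, and -0.23 with 3 at the floor, with Pgam1 -2.89, Slc2a3 2.09). Glycolysis sums, 4666 CPM (4058 to 5340) in adult lung and 4646 (4615 to 4677) in bone marrow, did not differ beyond counting error.

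By the ranking rule, genes furthest above bone marrow were C1qa (1238 against 8.56 CPM), Fn1 (531 against 1.03), Myl9 (1769 against 17.8), Ctss (663 against 4.77) and Lgals3 (531 against 3.47). They continued with C1qc (575 against 4.71), Cd79a (398 against 2.01), Hba-a1 (2123 against 32.0) and Cxcl2 (730 against 8.13). Single cells carried most of them: cell 3, with 118 macrophage marker UMIs, held 54 of 56 UMIs of C1qa, 28 of 30 of Ctss, 24 of 26 of C1qc and all UMIs of Fn1 (24), Lgals3 (24) and Cxcl2 (33), and cells 1 and 2 held all 18 of Cd79a. Myl9 UMIs were found in 9 and Hba-a1 UMIs in 7 of the 9 cells. The genes furthest below had 0 UMIs in adult lung: Stmn1 (742 CPM in bone marrow, so at least 11.2-fold lower), Ranbp1 (557 CPM, at least 8.39-fold), Pdia6 (492), Snrpd1 (488) and Ssb (477). The same held for the proliferation gene Mki67 (467 CPM, at least 7.04-fold), Cks2 (430 CPM, at least 6.49-fold), Ube2c (411), Vamp5 (382) and Hist1h1b (381). Markers of other cell types were higher too: macrophage markers had a median of 4.08 (10 of 11 higher, 0 lower) and monocyte markers 3.53 (5 of 8 higher, 0 lower, and 4.83 with 3 at the floor). B or plasma markers had 3.06 (5 of 8 higher, 1 lower, and 3.72 with 2 at the floor). Of the 151 macrophage marker UMIs, 118 lay in cell 3, and the B or plasma marker UMIs lay in cells 1 and 2 (28 and 38), so these medians rest mostly on 3 cells. Neutrophil markers had -2.00 (1 of 12 higher, 7 lower), with 11 at 0 in adult lung and a median of 2.00 at the floor. In the 672 genes with 10 or more UMIs in both libraries, the median log2 ratio was 1.58. That is the shift that median of ratios scaling removes, and with it the MHC class II median was 2.87. Those genes were picked by their UMIs in the shallow adult lung library, and over all 11950 measured genes the median was -0.84.

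Fetal lung against fetal liver megakaryocyte-like cells showed lower cell cycle RNA and higher megakaryocyte marker RNA by size. Those markers also named the clusters. Clusters 9 and 28 held 128 and 82 of the 236 fetal lung cells, against 120 and 10 of the 1444 fetal liver cells. The higher marker RNA was therefore not separated from the makeup of clusters. Of 10 MHC class II genes, 5 were higher by size but low in both tissues, and the Cd74 UMIs of fetal lung came from 0.847% of its 236 cells, against 2.03% of fetal lung endothelial-like cells (median depths 6366.5 and 34134 UMIs). Globin RNA and the imprinted gene Mest were also higher in fetal lung, and globin RNA was higher in its endothelial-like cells too.

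G2/M genes had a median log2 ratio of -2.07 (-2.18 to -1.97; percentile 0 of random lists), with 0 of 25 members higher and 24 at least 2-fold lower. They were led by Cenpf at -3.00, the mitotic activator gene Cdc20 at -2.75, Ube2c at -2.74 and Plk1 at -2.50. S phase genes had -1.64 (-1.80 to -1.57), with 23 of 23 lower, among them Tyms at -2.17, Ung at -2.12, Mcm2 at -2.10 and Rrm1 at -2.03. In cells taken by 6 or more markers, which in fetal lung were mostly macrophage-like, these medians were -0.46 and -0.27, and cluster 9 alone gave -0.81 for S phase. Megakaryocyte markers had a median of 1.35 (1.31 to 1.40; 11 of 18 higher, 0 lower), with the podoplanin receptor gene Clec1b at 2833 against 536 CPM, Alox12 at 2.38, Gp9 at 2.17 and the collagen receptor gene Gp6 at 2.16. Platelet signalling genes had 0.80 (7 of 21 higher, 0 lower, with P2ry12 3.13, Tbxas1 1.82, Mpig6b 1.56). Granule genes had 0.70 (6 of 19 higher, 0 lower, with Srgn 2.36, Thbs1 1.93, Clu 1.87) and cytoskeleton genes 0.64 (7 of 19 higher, 0 lower, with Pdlim1 2.35, Tuba4a 1.55, Mylk 1.48). These 3 medians turned to -0.29, -0.32 and -0.29 in cells with 6 or more markers. Megakaryocyte transcription factors had 0.20 (3 of 17 higher, 0 lower), with Gata2 at 1.73, Hhex at 1.36 and Nfe2 at 1.07.

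MHC class II presentation had a median of 0.98 (0.75 to 1.21), above all random lists, with 5 of 10 members higher and 0 lower. Cd74 stood at 37.2 (30.2 to 45.2) against 0.517 CPM (0.328 to 0.775), Lgmn at 2.35, Ctss at 2.20 and H2-Aa at 1.51. The list summed to 138 CPM (125 to 153) in fetal lung and 17.8 (16.6 to 19.1) in fetal liver. In fetal lung 2 of the 236 cells held 200 of its 372 UMIs and 172 of the 176 UMIs of H2-Aa, H2-Ab1, H2-Eb1 and Cd74, and the sum was 65.2 CPM (55.9 to 75.8) without them. After thinning, Cd74 was seen in 0.467% of 214 fetal lung megakaryocyte-like cells and in 0 of 259 endothelial-like cells (upper bound 1.41%), with 22 and 37 cells left out. The list's median was 0.21 in the part of the cells richer in megakaryocyte markers, 0.30 within cluster 9, 2.02 after thinning, and 2.04 and 0.38 with pseudocounts of 1 and 20 CPM. Co-stimulation genes had 0.86 (4 of 12 higher, 0 lower, with Tyrobp 2.12, Cd52 2.12, Fcgr3 1.84). Cytokines had 0.98 (9 of 19 higher, 0 lower, with Tnfsf14 2.82, Ccl3 2.80, Ccl4 2.63, Il1b 2.53), and within cluster 9 the medians of these lists were -0.49 and -0.05. Immediate-early genes had 0.85 (10 of 22 higher, 2 lower, with Nr4a1 4.12, Junb 2.66, Klf6 2.24) and 0.20 in the part richer in markers. The fetal programme list, made of imprinted and fetal growth genes, had 0.96 (8 of 17 higher, 2 lower), with Mest at 324 against 21.5 CPM, Meg3 at 2.40 and Cdkn1c at 1.70, and -0.21 under the strict cell filter. Secretory pathway genes had -0.57 (2 of 18 higher, 2 lower; the stress-response gene Ddit3 3.15, Dnajb9 1.93), glycolysis genes -0.65 (Slc2a3 1.60, Pfkl -1.40) and respiratory chain genes -0.51 (0 of 20 higher, 2 lower, with Cycs -1.27, Atp5g1 -1.14). Small medians were found for MHC class I presentation (0.09, with H2-T23 2.72) and innate sensors (-0.07, and 0.28 with 2 at the floor, with Myd88 -1.04). So it was for interferon response (-0.01, and 0.02 with 1 at the floor, with Rsad2 1.65) and growth factors (0.05, with Igf1 2.13, Pdgfa 2.00).

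The genes furthest above fetal liver were Hba-a1 (2504 against 75.7 CPM), Btg1 (575 against 25.2), Nr4a1 (148 against 3.77), Hist1h1c (2490 against 140) and Fam46c (150 against 4.90). They continued with Slc6a4, the serotonin transporter gene (506 against 28.1), Gadd45a (162 against 6.34), Ctla2a (10077 against 682), Hist1h2bc (2197 against 146) and Hbb-bt (1081 against 74.5). The genes furthest below were Cenpf (21.9 against 210 CPM), Cdc20 (22.7 against 180), Ube2c (63.2 against 449), Hmmr (26.7 against 181) and Gpatch4 (10.8 against 86.1). Then came Plk1 (13.4 against 99.3), Tipin (20.4 against 138), Lig1 (14.5 against 100.8), Ckap2l (21.2 against 135) and Nop56 (43.8 against 256). Macrophage markers had a median of 1.11 (8 of 12 higher, 0 lower; C1qb 55.4 against 4.92 CPM, C1qc 2.48, Trem2 1.59). Mesenchymal markers had 1.10 (6 of 10 higher, 0 lower), monocyte markers 1.00 (1.20 with 1 at the floor), B or plasma markers 1.06, T markers 1.11, NK markers 0.71 and neural markers 1.52. Those of erythroid cells had 0.14 (1.61 with 3 at the floor), with 6 of 14 higher and 1 lower. They summed to 4150 against 359 CPM in megakaryocyte-like cells and to 4827 against 503 CPM in endothelial-like cells, where the median was 1.75 (2.43 with 1 at the floor), so the shift in summed RNA was not particular to megakaryocyte-like cells. The shares of cells moved apart: Hba-a1 was seen in 54.2% of thinned and 61.9% of unthinned megakaryocyte-like cells of fetal lung, and in 5.41% and 20.3% of its endothelial-like cells. In fetal liver the shares were 5.89% and 29.4%, and 15.7% and 46.7%, so the share rose in megakaryocyte-like and fell in endothelial-like cells. Median depths were 6366.5 and 34134 UMIs in fetal lung and 28150 and 12298 in fetal liver, and thinning left out 22, 37, 18 and 4 cells. Over 8954 genes with 10 or more UMIs in both libraries the median log2 ratio was -0.28.

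Adult lung against fetal lung compared 9 with 236 megakaryocyte-like cells. MHC class II genes were higher by size in the adult cells and secretory pathway genes lower. Fetal programme and cell cycle RNA was lower when summed over members, while the signs of those medians turned with members at the floor. Megakaryocyte markers were alike. The 5 adult cells with leukocyte marker UMIs held most of the MHC class II RNA here too.

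All 8 measured MHC class II members were at least 2-fold higher, with a median of 5.10 (4.68 to 5.46): H2-Aa at 951 against 9.66 CPM, H2-Ab1 at 885 against 10.8, Cd74 at 2278 against 37.2 and H2-Eb1 at 663 against 7.80. Without the 5 adult cells with leukocyte marker UMIs, the median was -0.86, as most members were at 0 by depth. The 4 cells left summed to 675 CPM (292 to 1331) of the list from 8 UMIs, against 138 (125 to 153) in fetal lung. Adult lung neutrophil-like cells, a type that should hold little, summed to 596 CPM (286 to 1097), so the 4 cells were not above them beyond counting error. MHC class I presentation had 0.90 (-0.25 to 1.42; 6 of 12 higher, 1 lower, and 1.76 with 2 at the floor). It summed to 4554 CPM in those 5 cells, 3630 (2627 to 4889) in the 4 others and 765 in fetal lung. H2-K1 stood at 4.09, B2m at 3.43, H2-D1 at 3.03 and the immunoproteasome gene Psmb8 at 2.81. Co-stimulation genes had 2.75 (9 of 11 higher, 0 lower, with Cd86 4.33, Cd274 3.69, Fcgr2b 3.40), against -0.66 under the strict filter, and summed to 1567 CPM in fetal lung, between the sums of the 5 and the 4 adult cells given above. Innate sensors had 1.07 (-1.36 to 1.67; 3 of 5 higher, 2 lower, and 1.96 with 2 at the floor, with Cd14 3.36), against -1.49 under the strict filter. Immediate-early genes had 1.00 (10 of 19 higher, 3 lower, with Dusp1 3.45, Hsp90aa1 -2.35, Fos 1.93). They too were uneven, with 9978 CPM (8935 to 11109) in the 5 cells, 1097 (584 to 1876) in the 4 others and 6214 in fetal lung. Cytokines (-0.67; 1.00 with 5 at the floor, with Cxcl2 5.24), interferon response genes (-0.80; 2.56 with 7 at the floor, with Ifi27l2a 3.51) and growth factors (-0.86; 3.23 with 5 at the floor, with Pdgfa 4.36, Angpt1 3.04) gave no readable direction by their medians. Growth factors summed to 1459 CPM (1129 to 1857) in adult lung, with 1351 (772 to 2193) in the 4 other cells, against 218 (200 to 236) in fetal lung. Cytokines summed to 2145 (1739 to 2617) against 1614 (1567 to 1663), but to 929 (464 to 1661) in the 4 other cells. Interferon response sums, 597 (393 to 869) and 403 (380 to 428), overlapped.

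Imprinted fetal growth genes Mest, Cdkn1c, H19 and Meg3 had 0 UMIs in the adult lung cells, and the fetal programme list had a median of -2.18 (1 of 16 higher, 14 lower, and 1.78 with 13 at the floor). S phase genes had -2.17 (0 of 21 higher, 16 lower, and 1.503 with 17 at the floor) and G2/M genes -2.47 (0 of 23 higher, 22 lower, and 1.37 with 21 at the floor), so those medians too were bounded by depth. Sums in CPM differed beyond counting error: over members, G2/M genes made up 88.5 CPM (24.1 to 226) in adult and 912 (877 to 949) in fetal lung. S phase genes made up 111 (35.9 to 258) and 515 (489 to 543), and fetal programme genes 111 (35.9 to 258) and 820 (786 to 855). Secretory pathway genes had -3.29 (-3.94 to -2.72; 0 of 18 higher, 16 lower, and -1.95 with 6 at the floor), with Pdia3 at -3.61 and Sdf2l1 at 0 UMIs, and -0.49 in cells with 6 or more markers. Glycolysis genes had -1.04 (0 of 16 higher, 8 lower, and -0.85 with 3 at the floor, with Pgam1 -4.18) and respiratory chain genes -0.95 (0 of 20 higher, 10 lower, with Uqcrc1 -2.57). Megakaryocyte markers had -0.10 (-0.34 to 0.16; 1 of 18 higher, 2 lower, with Tubb1 2.04, Rab27b -1.03), with Slc35d3 at 0 against 192 CPM. Transcription factors had -0.92 (1 of 16 higher, 7 lower, and -0.78 with 3 at the floor, with Ets1 2.18) and signalling genes -0.38 (2 of 21 higher, 7 lower, and -0.27 with 4 at the floor, with Lat -4.24, P2ry12 2.55). Granule genes had -0.31 (-0.66 to 0.18; 0.62 with 4 at the floor, with Timp3 -3.46) and cytoskeleton genes 0.17 (-0.29 to 0.30; -0.24 under median of ratios scaling, with Coro1a -4.14).

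Genes furthest above fetal lung were the immunoglobulin gene Igkc (1592 CPM against 0 UMIs, so at least 1429-fold), H2-Aa, Fn1 (531 against 3.34 CPM) and H2-Ab1. Cd74, H2-Eb1, Cxcl2 (730 against 14.5), C1qa (1238 against 28.6) and Rnf19b (1061 against 35.3) came next. Cells 1 and 2 held all 72 Igkc UMIs, 35 of 43 of H2-Aa, 35 of 40 of H2-Ab1, 95 of 103 of Cd74 and 29 of 30 of H2-Eb1. Cell 3 held all UMIs of Fn1 (24) and Cxcl2 (33) and 54 of 56 of C1qa, while Rnf19b UMIs were found in 8 cells. Those furthest below had 0 UMIs in adult lung: the thrombin receptor gene F2r (454 CPM in fetal lung, so at least 6.85-fold lower), Sardh (442), Pdia6 (406), Mest (324 CPM, at least 4.88-fold) and Smim1 (298). The remaining ones were Tmem208 (295), Tecr (261), Atf4 (258), Ank3 (257) and Ddit3 (256). B or plasma markers had a median of 4.43 (5 of 5 higher, with Cd79b 4.46) and macrophage markers 3.09 (7 of 9 higher, 0 lower), carried mostly by the same 3 cells. Monocyte markers had 0.92 (-0.25 to 1.42; 2.75 with 3 at the floor) and erythroid markers -2.43 (0 of 9 higher, 6 lower, and -0.17 with 5 at the floor). Across 666 genes with 10 or more UMIs in both libraries the median log2 ratio was 0.41, but over all 9057 measured genes it was -1.03. The glycolysis and respiratory chain medians of this comparison, -1.04 and -0.95, lay near that value.

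Adult bone marrow against fetal liver was the deepest comparison, with 497 and 1444 megakaryocyte-like cells. Antigen presentation, immediate-early and stem or progenitor genes were higher by size in the adult bone marrow cells. Glycolysis genes and 8 of 17 fetal programme genes were lower by size, while S phase and G2/M genes were close to equal. The S phase median was -1.33, however, in 1 of 20 settings.

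MHC class I presentation had a median of 2.54 (2.43 to 2.63), above all random lists, with 11 of 15 members higher and 0 lower. H2-K1 stood at 858 against 66.9 CPM, H2-Q7 at 6.25 and the immunoproteasome genes Psmb8 at 3.86 and Psmb9 at 3.82. H2-K1 was seen in 96.6% of the bone marrow cells, and the 50 cells with most held 22.1% of its UMIs. MHC class II presentation had 1.83 (1.69 to 1.97; 6 of 11 higher, 0 lower), with Cd74 at 49.2 against 0.517 CPM, H2-DMa at 71.5 against 5.46, H2-Aa at 2.15 and H2-DMb1 at 2.09. Its members were spread differently over cells: H2-DMa was seen in 82.7% of the bone marrow cells and in 2.61% of neutrophil-like cells (71.5 against 3.75 CPM), and Cd74 in 8.05% and 1.71% (median depths 32225 and 4497 UMIs). After thinning, which left out 6 and 134 cells, the Cd74 shares were 2.24% and 0.615% and those of Igkc 5.50% and 6.05%. All Cd74, H2-Aa and H2-Eb1 UMIs lay within 50 of the 497 cells. Without the 23 cells of cluster 40, whose top genes included Igkc and S100a9, Cd74 stood at 25.6, H2-Aa at 7.01 and H2-Eb1 at 6.46 CPM, H2-DMa at 72.3, and the MHC class II median was 1.12. Igkc was seen in 53.1% of these cells against 16.3% of neutrophil-like cells (975 against 26.3 CPM), and 50 cells held 98.5% of its UMIs. Without the bone marrow cells with 5 or more immunoglobulin UMIs, 479 cells were left and the MHC class II median was 1.01, and it was 0.87 with a pseudocount of 20 CPM.

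Interferon response genes had 0.84 (5 of 20 higher, 0 lower; Ifit1 37.5 against 0.427 CPM, Rsad2 1.57, Ifitm3 1.55, Xaf1 1.12), 1.30 with a pseudocount of 1 CPM and 0.30 with 20 CPM. Ifit1 was mostly RNA of cluster 40: without it, Ifit1 stood at 1.39 CPM and the interferon median was 0.49. Immediate-early genes had 1.12 (1.06 to 1.17; 12 of 22 higher, 0 lower; Dusp1 124 against 17.7 CPM, Fos 369 against 66.6, Atf3 2.32, Fosb 2.02). Stem or progenitor markers had 1.13 (8 of 12 higher, 0 lower), with the stem cell transcription factor gene Hlf at 1.87, Kit at 1.60, Sox4 at 1.48 and Mecom at 1.31. Of the 497 bone marrow cells, 240 and 208 lay in clusters 10 and 17, which were named stem or progenitor-like with clusters named by fold over all other cells, so this difference was not separated from the choice of cluster names. The innate sensor (0.12, with Irak3 1.42), co-stimulation (0.14, with Ptprc 1.95, Fcer1g -1.32), cytokine (0.07, with Ccl3 -1.18) and growth factor (0.05, with Pdgfa 1.54, Pdgfb -1.14) lists had small medians. S phase genes had 0.17 (1 of 23 higher, 0 lower, with E2f8 1.29) and G2/M genes -0.05 (0 of 25 in either direction). Over 20 settings the S phase median ranged from -1.33 to 0.40, and it was negative in 1 of them.

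Fetal programme genes had a median of -0.89 (0 of 17 higher, 8 lower, and -1.23 with 4 at the floor, and -0.30 with a pseudocount of 20 CPM). The RNA-binding protein gene Igf2bp3 (chromosome 6, 49085223 to 49214957) stood at 2.06 against 65.1 CPM and Lin28b (chromosome 10, 45376620 to 45486395) at 0.217 against 26.7 CPM. Igf2bp1 and H19 had 0 UMIs in bone marrow, against 19.1 and 13.9 CPM. Glycolysis genes had -1.17 (0 of 16 higher, 10 lower), with the lactate exporter gene Slc16a3 at -3.64, the glucose transporter gene Slc2a1 at -2.19, Pgam1 at -2.02 and Aldoa at -1.70. Respiratory chain genes had -0.02 (0 of 20 in either direction). Cytoskeleton genes had -0.78 (0 of 19 higher, 7 lower, with Tpm4 -1.80, Actn1 -1.50, Flna -1.40). Platelet signalling genes had -0.77 (2 of 21 higher, 5 lower, with Mpig6b -1.89, P2ry12 1.42, F2r -1.27). With clusters named by fold over all other cells these medians were -0.14 and 0.23. Granule genes had -0.39 (3 of 19 higher, 3 lower, with Thbs1 -3.56, Selp 2.07, Serpine2 2.04, Sparc -1.51) and secretory pathway genes -0.26 (0 of 18 in either direction, with Hsp90b1 -0.89). Megakaryocyte markers had -0.98 (0 of 18 higher, 8 lower, with Ppbp -1.88, Alox12 -1.85, Gp9 -1.41), and transcription factors 0.02 (1 of 17 higher, 2 lower), with Gata2 at 137 against 32.4 CPM and Gata1 at 58.4 against 137.

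The genes furthest above fetal liver included Igkc (975 CPM against 0 UMIs, so at least 14470-fold), Ighm (563 against 0.135), Jchain (116 against 0.0899), Mndal (62.9 against 0.112) and H2-Q6 (60.7 CPM against 0 UMIs, at least 901-fold). H2-Q7 stood at 382 against 0.0674 CPM from 3 UMIs, a ratio of 5661 (1936 to 27459). Serpina3g (171 against 5.66 CPM), Psmb8 (306 against 16.4), Psmb9 (124 against 4.09) and the interferon-induced gene Ly6e (217 against 11.8) completed the ranking. Furthest below were Sardh (15.5 against 307 CPM), Hpgd (8.51 against 177), Slc16a3 (13.8 against 229), Ppp1r14a (4.01 against 106), Ank3 (7.15 against 139) and Spns1 (27.3 against 378). Thbs1 (69.7 against 878), Hbb-bt (2.28 against 74.5), Myl9 (17.8 against 243) and Igf2bp3 followed. Neutrophil markers had a median of 1.95 (7 of 12 higher, 0 lower, and 2.36 with 2 at the floor), with S100a9 at 199 CPM in bone marrow megakaryocyte-like cells against 181215 CPM in bone marrow neutrophil-like cells, and Camp at 3.07. B or plasma markers had 0.37 (0.74 with 1 at the floor; 3 of 8 higher, 0 lower). Erythroid markers had -0.80 (-1.11 with 3 at the floor; 0 of 14 higher, 6 lower) and endothelial markers -0.49 (-1.13 with 3 at the floor; 0 of 11 higher, 3 lower). The median log2 ratio of 11549 genes with 10 or more UMIs in both libraries was 0.08.

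**Figure D3:**
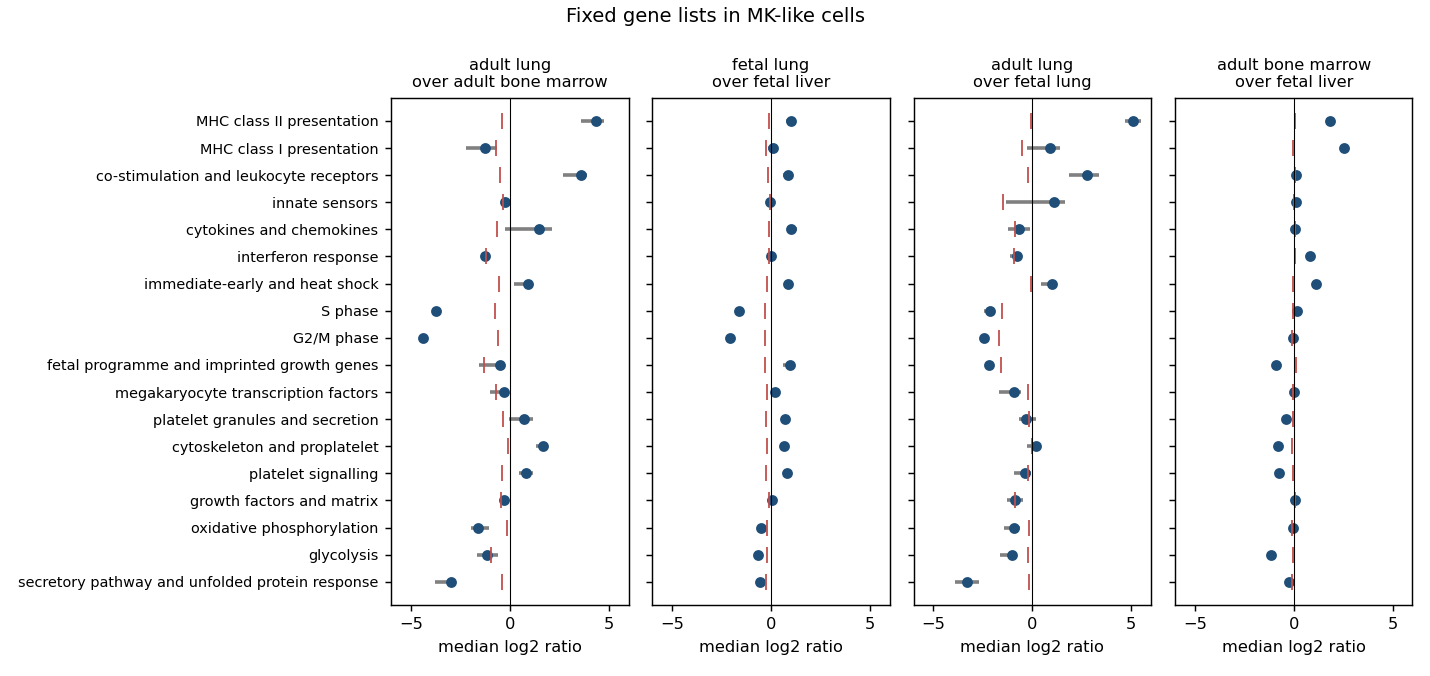
Median log2 ratio of each fixed gene list in megakaryocyte-like cells, with its counting interval and the median of matched random lists. The MHC class II median was 4.33 for adult lung over adult bone marrow, 0.98 for fetal lung over fetal liver, 5.10 for adult over fetal lung and 1.83 for adult bone marrow over fetal liver.

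Over all kept cells, MHC class II genes had median log2 ratios of 3.06 for adult lung over adult bone marrow (12 of 12 higher) and 0.42 for fetal lung over fetal liver (4 of 11). The values were 4.17 for adult over fetal lung (11 of 12) and 2.43 for adult bone marrow over fetal liver (7 of 12, with 1 lower). Megakaryocyte markers had -2.26, -0.97, -2.77 (-2.91 with 1 at the floor) and -1.67 in the same comparisons, and G2/M genes -2.73, -0.28, -2.23 and 0.04. The fetal programme had 0.26, 1.11, -3.35 (-3.51 with 1 at the floor) and -2.49 (-2.82 with 4).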

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

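Of the tests below, the 2 on G2/M genes were written down before their results were seen, and the other 7 were chosen after. The list differences and the left-out barcodes were not tested.

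For 5 fixed lists, the medians of the same contrast had opposite signs in 2 settings of the design, each beyond counting error, and the difference between them was not tested. Lung over the blood-forming organ gave the fetal programme list a median log2 ratio of -0.50 in adults and 0.96 in fetuses, and megakaryocyte transcription factors -0.30 and 0.20. Adult over fetal gave cytokines and chemokines -0.67 in lung and 0.07 in the blood-forming organs, interferon response genes -0.80 and 0.84, and S phase genes -2.17 and 0.17. Among matched random lists, the percentiles in that order were 80.3 and 100 for the fetal programme and 65.5 and 94.95 for transcription factors. They were 67.0 and 45.2 for cytokines, 90.4 and 100 for interferon response genes and 8.7 and 99.0 for S phase genes. For the fetal programme, transcription factor and interferon response lists, both sides thus lay above the middle of matched lists. Each of these pairs includes the 9 adult lung cells, in which many members had 0 UMIs. With those members at 3 UMIs, the adult lung median turned to 2.54 for the fetal programme, 1.00 for cytokines and chemokines, 2.56 for interferon response genes and 1.503 for S phase genes, and was -0.05 for transcription factors. The adult lung medians therefore had no settled direction for the fetal programme, cytokine and interferon response lists. Summed over members, cytokine RNA was higher in adult than in fetal lung, at 2145 CPM (1739 to 2617) against 1614 (1567 to 1663). Without the adult lung cells with leukocyte marker UMIs the sum was 929 CPM (464 to 1661), which was not above fetal lung. S phase RNA summed over members was lower in adult than in fetal lung, at 111 CPM (35.9 to 258) against 515 (489 to 543). In the blood-forming organs the S phase median of 0.17 turned to -1.33 in 1 of 20 settings.

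Barcodes left out by the cell filter held megakaryocyte marker RNA. Among UMIs outside mt- genes, these markers made up 1.18% (1.14 to 1.22) in 409 adult bone marrow barcodes, 0.355% (0.330 to 0.381) in 146 adult lung barcodes, 1.05% (1.03 to 1.07) in 579 fetal liver barcodes and 0.784% (0.748 to 0.821) in 146 fetal lung barcodes. Kept cells held 0.920%, 0.171%, 2.45% and 0.920%, so the left-out share was higher than theirs in both adult libraries and lower in both fetal ones. There was no control sample, and the limits at a count of 0 (0.00100%, 0.00138%, 0.000223% and 0.00131%) would be passed by a few UMIs. Left-out barcodes with high mt- shares had median mt- shares of 97.2%, 27.1%, 75.6% and 74.4%.

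MHC class II RNA in adult lung megakaryocyte-like cells was weighed first. Free RNA would spread over cells with their depth, but 2 cells held 89.8% (85.0 to 93.5) of 216 UMIs of 4 class II genes and 31.5% of all UMIs, which argues against free RNA as the source of most of it. Another leukocyte in the same barcode is a candidate explanation: the 5 cells with 5 or more UMIs of B or plasma, macrophage and dendritic markers held 11.9 times (5.95 to 27.8) the list CPM of the 4 others, and the cells with most class II UMIs held Igkc and Cd79a or C1qa. It need not explain all of it, since the 4 others still held 675 CPM (292 to 1331) from 8 UMIs, against 218 in bone marrow megakaryocyte-like and 596 (286 to 1097) in adult lung neutrophil-like cells. Megakaryocytes of the adult lung that make both kinds of RNA stay open, since a cell of mixed expression and a pair of joined cells look alike here. The 2 cells with most class II UMIs lay in the low-gene cluster 28. Whether its barcodes were nucleated cells was not tested, so leukocytes with bound platelets were not told apart from megakaryocytes either.

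Megakaryocyte RNA in fetal lung macrophage-like cells was weighed second. Itga2b was 25.9 times as high (22.96 to 29.2) in those cells as in endothelial-like cells of the same library, 591 against 22.9 CPM, which argues against free RNA. Mesenchymal-like cells of that library held 219 CPM, and 44 of those 381 cells held 6 or more Itga2b UMIs against 8 of 296 endothelial-like cells, so the pattern was not confined to macrophage-like cells. Of 725 macrophage-like cells, 260 (231 to 291) held 6 or more Itga2b UMIs against 3.06 expected from chance pairs in a droplet. Gata1 UMIs, which mark nucleated megakaryocytes, numbered 12.9 per 100 Itga2b UMIs in cluster 15 of fetal lung, with 11.1 in cluster 9. They numbered 1.69 in the low-gene cluster 28, which stood in for platelets, so the ratio of clusters 15 and 28 was 7.63 (5.06 to 12.1). For the 198 fetal lung cells of cluster 15, this argues against platelets on or in macrophages as the whole source. The other macrophage-like cells were not covered. Whole megakaryocytes bound to or taken up by macrophages, or bound to other cells, before or after tissue was dissociated, may explain the pattern and were not tested.

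Lower cell cycle RNA in fetal lung than in fetal liver megakaryocyte-like cells was the last pattern weighed. Within cluster 9, with 128 and 120 cells, the G2/M median was -1.57 (-1.83 to -1.47). This argues against the share of cells per cluster as the whole cause of the lower G2/M RNA. The cluster 9 sums were 1398363 UMIs in fetal lung and 2311556 in fetal liver, at median depths of 8233.5 and 8689.5 UMIs. Deep cells thus weighed more in the fetal liver sum, and the makeup within cluster 9 was not matched. The S phase median within cluster 9 was -0.81 (-0.99 to -0.53), against -1.64 over all megakaryocyte-like cells of these libraries. For S phase genes the makeup of clusters therefore stays open as a cause of part or more of the difference. Without cluster 28, with 154 and 1434 cells, the G2/M median was -1.93 (-2.08 to -1.88) and the S phase median -1.59 (-1.76 to -1.52). The barcodes of cluster 28 therefore did not account for most of the difference. Leaving them out could move these medians only little, because its 82 fetal lung barcodes had a median of 3690.5 UMIs in a sum of 2691640. For barcodes with few genes in general this test could not decide, because 128 of the 154 fetal lung cells left were in cluster 9. Those had a median of 2215.5 genes, against 4748 and 5419 in fetal liver clusters 0 and 2. A difference between the tissues, a difference in handling and an effect of the sort gate stay open, because each tissue had 1 library.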

How the results depend on the processing

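Cluster 9 alone, leaving out adult lung cells with leukocyte marker UMIs, leaving out bone marrow cells with immunoglobulin UMIs, members above the floor, leaving out cluster 40 and names by fold over all other cells were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Where nothing else is said, the cause was not tested.

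Of 75 alternative values of the MHC class II medians, 40 stayed within their counting interval, 33 moved beyond it and 2 changed sign. Of 1269 alternative values of the other list medians, 833 stayed within, 420 moved and 16 changed sign from a value of 1 or more in size. Of the 26 list medians of 1 or more in size, 9 had the opposite sign in some setting, and of the 46 smaller ones, 32 did. The megakaryocyte-like shares moved in 10 of 32 values, the shares of other classes in 60 of 256 and the sort genes in 84 of 96. Of 2 macrophage-like list medians, 1 moved. The MHC class II median ranged from -0.65 to 5.02 for adult lung over adult bone marrow, 0.21 to 2.04 for fetal lung over fetal liver, -0.86 to 7.63 for adult over fetal lung and 0.87 to 2.56 for adult bone marrow over fetal liver.

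With the loose cell filter, the megakaryocyte-like share was 1.12% in adult lung and 16.0% in fetal lung, and the MHC class II median of adult over fetal lung was 4.05. With the strict filter, the share was 23.8% in adult bone marrow, 0.166% in adult lung and 11.3% in fetal lung, and only 3 adult lung cells were left. The strict filter gave -0.41 for cytokines in adult lung over adult bone marrow, and 6.79 for MHC class II, -0.66 for co-stimulation and -1.49 for innate sensors in adult over fetal lung. With the fixed lists left in the clustering genes, cytokines had -0.18 in adult lung over adult bone marrow, and adult over fetal lung gave 5.47 for MHC class II, -0.46 for co-stimulation and -1.09 for innate sensors, with 8 adult lung cells.

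Cells with 6 or more megakaryocyte markers made up 6.84% of adult lung, 77.9% of fetal liver and 43.8% of fetal lung. They gave MHC class II medians of 4.93 (adult lung over adult bone marrow), 0.50 (fetal lung over fetal liver) and 1.42 (adult bone marrow over fetal liver), and 0.0942 for MHC class I and 1.02 for interferon response in adult lung over adult bone marrow. By construction this definition takes in macrophage-like cells with megakaryocyte RNA, which were 60.3% of those cells in adult lung and 50.4% in fetal lung. In the upper part by megakaryocyte marker share, MHC class II had 0.21 in fetal lung over fetal liver, 7.63 in adult over fetal lung and 2.21 in adult bone marrow over fetal liver, cytokines had -0.50 in adult lung over adult bone marrow, and innate sensors had -1.66 and immediate-early genes -0.72 in adult over fetal lung. Cluster 9 alone gave 0.30 for MHC class II in fetal lung over fetal liver. Clusters named by fold over all other cells gave shares of 1.71% in adult bone marrow and 38.5% in fetal liver, and MHC class II medians of 2.77 (adult lung over adult bone marrow), 1.28 (fetal lung over fetal liver) and 2.56 (adult bone marrow over fetal liver).

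Without the 5 adult lung cells with leukocyte marker UMIs, MHC class II had -0.65 over adult bone marrow and -0.86 over fetal lung, co-stimulation -0.37 and -1.18, cytokines -0.41 over adult bone marrow, and innate sensors -1.44 and immediate-early genes -3.27 over fetal lung. With 11847 UMIs left in 4 cells, most members are at 0 there by depth. Without the bone marrow cells with immunoglobulin UMIs, MHC class II had 4.84 in adult lung over adult bone marrow and 1.01 in adult bone marrow over fetal liver. Without the 23 cells of bone marrow cluster 40, the same medians were 4.98 and 1.12, and interferon response had 0.49 in adult bone marrow over fetal liver.

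Totals without mt-, ribosomal and haemoglobin genes gave 2.05 for MHC class II in adult bone marrow over fetal liver, and Itga2b at 554 CPM in adult bone marrow, 59.8 in adult lung and 626 in fetal lung, as smaller totals must. The value of Itga2b, CPM in kept cells, fetal liver, was 939. Median of ratios scaling gave 2.87 in adult lung over adult bone marrow. Thinning gave MHC class II medians of 2.02 (2.018) in fetal lung over fetal liver, 5.71 in adult over fetal lung and 2.02 (2.023) in adult bone marrow over fetal liver. In the order of the ranges above, a pseudocount of 1 CPM gave 5.02, 2.04, 5.55 and 2.41 and a pseudocount of 20 CPM 2.76, 0.38, 4.28 and 0.87, as a larger pseudocount draws ratios to 0. Members with 50 or more UMIs gave 1.44 in fetal lung over fetal liver and 5.73 in adult over fetal lung, and members above the floor gave 5.71 (5.706) in adult over fetal lung. Without thinning, Itga2b was seen in 24.4%, 10.3%, 85.3% and 52.7% of cells of adult bone marrow, adult lung, fetal liver and fetal lung.

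Depth limited the adult lung values more than those of the other libraries: with 45222 UMIs in 9 cells, the 3 UMIs used as the floor for a gene at 0 come to 66.3 CPM. Cluster 9 alone was used for fetal lung over fetal liver only, since bone marrow had 1 such cell and adult lung 4.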

Other observations

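No test in this part was planned, since its comparisons of other cell classes were chosen after the megakaryocyte-like results were seen. Macrophage-like cells of adult lung (963) and fetal lung (725) lay in different clusters. Adult cells held higher RNA by size of Chil3 (5122 CPM against 0 UMIs), H2-Aa (1816 against 0.174 CPM, from 3 UMIs), Ccl8, Ear2 (716 against 0.405), Cd209f (551 against 0 UMIs) and Plet1. The MHC class II median was 3.42, with 9 members higher and 1 lower. Fetal cells held more Hba-a1 (602 against 13.7 CPM), the platelet gene Treml1 (488 against 17.5), Crybb1 (126 against 1.94) and Mest (115 against 1.65). S phase genes had -1.39 and G2/M genes -1.70 in adult over fetal cells. Megakaryocyte markers had -2.98 (-3.02 with 1 at the floor), and -0.84 without cluster 15.

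Endothelial-like cells of adult lung (382) held more Gsn (2618 against 5.96 CPM), Ly6a (2312 against 5.22), Emp2 (996 against 0.571) and Inmt (1105 against 0 UMIs) than those of fetal lung (296). MHC class I genes had a median of 3.36 (15 higher, 0 lower), MHC class II genes 2.76 (11 higher, 0 lower, and 5.26 with 4 at the floor) and interferon response genes 2.31 (20 higher, 0 lower). MHC class II RNA summed to 1630 CPM in these cells and to 596 CPM in adult lung neutrophil-like cells. Markers of other classes moved with them: mesenchymal markers had a median of 4.21 (11 of 12 higher; 1547 against 22.6 CPM), B or plasma markers 1.34 (7 of 9 higher, and 3.83 with 4 at the floor; 315 against 42.4 CPM), lung epithelial markers 1.30 (2.25 with 4 at the floor) and macrophage markers 0.69 (0.90 with 4 at the floor; 1436 against 292 CPM). G2/M genes had -4.15 (0 higher, 25 lower, and -4.50 with 3 at the floor), S phase genes -2.88 and the fetal programme -2.60 (-2.82 with 3 at the floor), with Mest at 14.1 against 2248 CPM. Fetal lung endothelial-like cells held more Rgcc (319 against 2.74 CPM) and Foxf1 (154 against 1.92) than those of fetal liver (259), where Ehd3 (954 against 6.28), Stab2 (611 against 12.7) and Mrc1 (506 against 8.90) were higher. Macrophage markers, of which Mrc1 is one, moved the same way, with a median of -2.59 for fetal lung over fetal liver (0 higher, 9 lower; 292 against 4869 CPM), and neutrophil markers had -3.78.

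Those endothelial-like cells lay in different clusters: 240, 82 and 53 of the adult lung cells in clusters 11, 30 and 34, 225 and 70 of the fetal lung cells in clusters 12 and 32, and 258 of the fetal liver cells in cluster 7. Cluster 30 was named mesenchymal-like when clusters were named by fold over all other cells. Inmt was also a top gene of the mesenchymal-like cluster 33, so differences in the makeup of the class were not separated from differences within a cell type.

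Basophil or mast-like cells of adult bone marrow (70) held more of the granule protease genes Prss34 (36877 against 321 CPM) and Mcpt8 (20129 against 366) than those of fetal liver (43). The mast cell gene Cma1 was lower (1.60 against 115 CPM, with 1 UMI in adult bone marrow, so 72.0 times as high in fetal liver, 12.6 to 2879), so the mix of basophils and mast cells was not held equal. Their MHC class I median was 1.37 and their fetal programme median -2.92 (-2.77 with 6 at the floor). Markers of other classes moved too: neutrophil 3.02 (7 of 8 higher, and 3.06 with 4 at the floor), granulocyte-monocyte progenitor 1.98 (4 of 6 higher), megakaryocyte -2.14 (12 of 13 lower, and -2.06 with 5 at the floor) and erythroid markers -2.12 (5 of 6 lower, and -1.96 with 3 at the floor).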
